A study of Triticum aestivum with 78 samples.

How the data were processed

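The data are 78 Affymetrix wheat expression arrays of developing seed from 39 lines of 1 mapping population, with 2 biological replicates per line. Per the labels, each sample filled a tube with seed taken 5 days after spikes were tagged at anther emergence, poly(A) RNA was purified and biotin-labelled cRNA was hybridized, and the field trial was a lattice of 49 entries with 3 replications. The labels do not say which field replication each array came from, and they give no measure of seed stage other than the day. The deposited values are intensities that the authors made with RMA, per the submitters' processing notes, which give no version. RMA subtracts background, normalizes the arrays to a common distribution and summarizes the probes of each probe set. The design had assumed log2 values, but the deposited intensities are linear (5.04 to 27696), so log2 was taken first and no constant was added. The raw probe intensities were not analysed here, so the background step and the probe summary could not be varied.

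The files hold 61290 probe sets. From these, 111 control and 64 reporter probe sets were left out of the tests, which left 61115. Gene symbols came from the annotation of the array's probes, and names and synonyms from the table of the Chinese Spring RefSeq v2.1 assembly, which was used for names only. There, 1273 probe sets had 1 gene symbol, 0 had several and 59842 had none, and 1272 matched a gene of that assembly. A total of 200 probe sets of 102 genes counted as named, with a symbol or synonym other than a locus number, and 147 of them had a highest line mean at or above the median level of all probe sets, 5.07 log2 units. No coordinates were used. Sequences of the probes were not analysed, so a base difference between the parents under a probe could not be told from a difference in level.

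The genotype effect was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), as the moderated F over 39 lines, with Benjamini-Hochberg adjusted p below 0.05. The same fit, which shares 1 estimate of spread between lines, gave the contrast of each line with the mean of the others and of F38a with F38b. The intraclass correlation was the variance between lines as a share of the total. A probe set with a genotype effect counted as dividing the lines into 2 classes if the largest gap between neighbouring line means that left at least 6 lines on each side was at least 0.5 log2 units and at least 2 residual SDs. An exact two-sided binomial test compared the classes with equal numbers, and identical or mirror splits were counted against 1000 draws in which each split was permuted over the lines. Replicate 2 was compared with replicate 1 in limma with line as a block. Agreement of replicates was the number of arrays whose most correlated other array belonged to the same line.

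The named genes followed a rule written before the data were examined. It took named probe sets that reached the median level: the 10 with the largest SD between lines among those with an intraclass correlation of at least 0.8, of which there were none, and the 2 with the largest F of each list. For H8 and A35, the lines with most calls, and for F38a against F38b it took the 3 highest and 3 lowest past the threshold, and for replicate 2 against 1 the 5 highest and 5 lowest. Other named probe sets with a genotype effect, and probe sets without an annotated gene, were named after their values were seen.

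Gene lists were fixed before the data were examined as patterns to search in gene descriptions. The annotation holds symbols in place of descriptions, so only 7 of 18 planned lists had any member and 2 had 3 or more probe sets, the number needed for a test. In their place 10 lists of symbols were added, chosen on the names alone before any level was looked at. The share of a list's probe sets with a genotype effect was compared with 10000 random lists matched on mean level in 50 bins (two-sided), adjusted over 12 lists, and also with 1 probe set per gene and by Fisher's exact test. A list mean was the mean over members above the median level of the log2 value less the probe set's mean over all arrays. It was tested for 9 lists with a one-way F and 100000 permutations of the arrays, and between replicates by 100000 changes of sign. Correlations of list means used 100000 permutations, two-sided. These steps and the figures ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

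Per the instrument files, all arrays were read on 1 scanner over 15 scan days, in 2 campaigns that coincide with the replicate numbers. A single scan day held arrays of both campaigns and 3 days held 1 array each. The arrays B68 replicate 2 (wash aborted), D15 replicate 2 (no protocol recorded) and H8 replicate 1 (another protocol) differed in their wash record. The number of arrays limits the precision of every value. To see whether replicate numbers pair the arrays, differences between the replicates were correlated between lines: the median was 0.14, and 422 pairs of lines exceeded 0.1, so the replicate number was also tried as a replicate block, which called 5622 probe sets with a genotype effect, among them all 4088 found without it. RNA integrity was followed as the 3′ minus 5′ difference of 4 wheat control genes.

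Sample identity was examined with a panel chosen without the line labels: probe sets whose sorted values had a gap of at least 0.6 log2 units with at least 10 arrays on each side (145 probe sets), reduced to 73 splits by dropping those agreeing at 90% or more with another. A line's arrays were called disagreeing if they agreed at no more than the upper end of the central 95% of pairs of arrays from different lines, 67.1%. The panel, the limit, the alternatives without lines, without the 3 arrays with a differing wash record or with the 3′ minus 5′ covariate, scan day in the replicate comparison, and the correlations of replicate differences were chosen after the data were seen. The other alternatives were fixed before: further scaling, only probe sets above the median level, the replicate block, scan day as a fixed or random term in the other comparisons, array weights, other thresholds and tests, and leaving out each array in turn. Where that left a line with 1 array, limma's shared estimate took its spread to be like that of the other lines.

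The steps were tested on simulated data with the same number of lines. Of 200 probe sets with a line SD of 0.25 log2 units 51% were recovered, of 200 with 0.5 log2 units 92.5%, and of 200 in 2 classes 1 log2 unit apart 90.5%, although only 38 of those met the gap rule, against 179 of 200 at 2 log2 units. Among 60315 probe sets without an effect 26 were called. These simulated arrays had independent noise, with no replicate difference, outlying array or exchanged label. Effects were placed only in probe sets at or above the median level. The shares recovered and called therefore need not hold for the real arrays. For simulated lists of 10, 84 of 100 with a line SD of 0.1 log2 units passed an unadjusted permutation p of 0.05, and 8 of 100 without an effect did.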

Results

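Transcript levels were measured in developing seed of hexaploid wheat, collected 5 days after anthesis from field plots. The plants were 39 lines of a mapping population from the cross RL4452 x AC Domain, and each line gave 2 biological replicates, for 78 Affymetrix wheat arrays. The parents were in the same field trial, but no array of them is in the series. The values are RMA intensities, which ran from 5.04 to 27696 on a linear scale and were taken to log2 units here. Array medians lay between 32.1 and 36.4 intensity units. Of 61115 probe sets tested, 1273 had a gene symbol, and these represented 771 genes. Values are mean log2 intensity ± SD of 2 replicate arrays unless stated otherwise, and the small number of arrays per line limits the precision of each line mean.

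The first comparison asked which transcripts differed in level between lines. Genes of starch and fructan metabolism and of grain protective proteins were among the named genes with the widest ranges. GBSS, the granule-bound starch synthase encoded by the waxy locus, had 11.35 ± 0.34 in line A81 and 7.43 ± 0.35 in line J15, a 15.1-fold range. The fructan exohydrolase 6-FEH had 10.42 ± 0.04 in J15 and 7.00 ± 0.93 in E5, a 10.7-fold range. GLU1A, a beta-glucosidase, had 10.06 ± 0.63 in A77 and 6.17 ± 0.08 in C25, and the small heat shock protein gene hsp16.9A had 6.85 ± 0.87 in B68 and 3.47 ± 0.05 in G32. In limma's moderated F test across the 39 lines, the adjusted p was 1.02e-05 for GBSS, 3.6e-05 for 6-FEH, 1.91e-05 for GLU1A and 6.14e-05 for hsp16.9A. A further probe set of 6-FEH, Ta.9641.1.A1_a_at, passed with a 4.80-fold range between B33 and E5 (adjusted p = 0.00692). Single arrays moved these ranges: hsp16.9A had 6.83-fold without B68 replicate 1 and 16-fold without B68 replicate 2, and the 6-FEH probe sets had 16.9-fold without E5 replicate 1 and 7.99-fold without B33 replicate 2.

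Inhibitors of alpha-amylase and trypsin and the purothionins, small seed proteins linked to defence, had their highest mean in 1 line, F36, through its replicate 1 array. ATI, a name shared by more than 1 annotated alpha-amylase/trypsin inhibitor gene, was represented by 4 probe sets with a genotype effect, with ranges of 42.1-fold to 55.4-fold. Without F36 replicate 1 these were 22.5-fold to 34.1-fold and F87 was highest at all 4, and without F36 replicate 2 they were 94.8-fold to 164-fold. The ATI probe set with the largest F was of a different annotated gene from the other 3. It had 9.87 ± 2.22 in line F36 and 4.08 ± 0.14 in B33 (limma adjusted p = 0.00106). THI1.1, a purothionin gene, had 10.41 ± 1.77 in F36 and 4.69 ± 0.06 in DH91, a 52.6-fold range (adjusted p = 0.00967). The purothionin genes THI1.2 and Pur-A1 and the monomeric alpha-amylase inhibitor gene CIII were also highest in F36, with ranges of 7.38-fold, 27.4-fold and 6.72-fold (adjusted p = 0.0164, 0.0049 and 0.00415). The avenin-like storage protein gene avnla had 7.87 ± 2.68 in F36 and 3.41 ± 0.10 in F29 (22-fold, adjusted p = 0.0199). The lowest line means of hsp16.9A, 3 of the 4 ATI probe sets, THI1.1, CIII, Pur-A1 and avnla lay below the median level of all probe sets, 5.07, and were not shown to exceed background, so their fold ranges hold for intensities only. Within F36 the replicate arrays lay far apart, which the SDs of 1.27 to 2.68 for these genes reflect. Without F36 replicate 1 the ranges were 3.61-fold for CIII, 13.4-fold for Pur-A1 and 5.91-fold for avnla. Without F36 replicate 2 they were 13.4-fold, 60.5-fold and 81.8-fold, with 125-fold for THI1.1 and 13.8-fold for THI1.2, and THI1.2 had 14.7-fold without H5 replicate 1, with H5 highest. Without the F36 replicate 1 array the adjusted p of avnla was 0.148, against 0.000323 to 0.148 over all arrays left out in turn. A second Pur-A1 probe set, Ta.1308.1.S1_at (adjusted p = 0.0319), lost its call without F36 replicate 1, D15 replicate 1, F44 replicate 2 or either F87 array, with values up to 0.0904. With scan day in the model the probe sets of THI1.1 and THI1.2 named here reached 0.0834 and 0.125, their highest values over the alternatives.

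**Figure D1:**
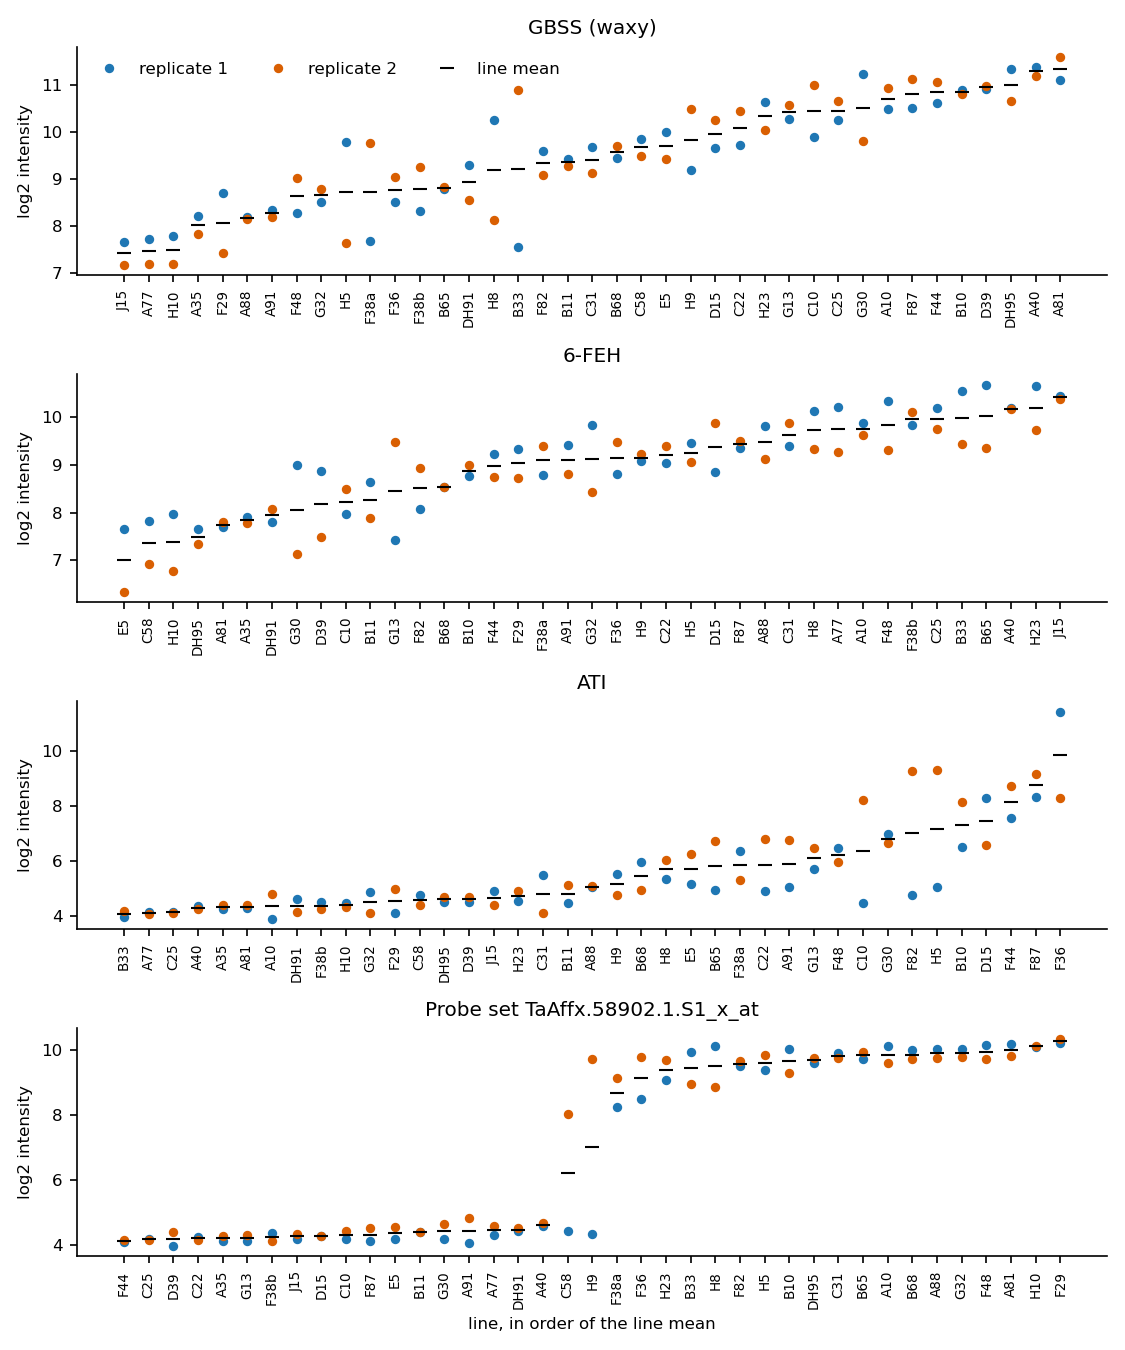
Log2 intensity of 3 named genes and of 1 probe set without an annotated gene on each array (points, replicate 1 in blue and replicate 2 in orange) with the mean of each line (bars), lines ordered by their mean in each panel. GBSS ran from 7.43 to 11.35 and 6-FEH from 7.00 to 10.42, ATI was highest in F36 at 9.87, and probe set TaAffx.58902.1.S1_x_at had 19 lines above and 20 below its largest gap.

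In all, 4088 of 61115 probe sets (6.69%) had a genotype effect at an adjusted p below 0.05. The share was 10.9% among probe sets with a mean level above the median and 2.51% among the others. Among the 4088 the median range between the highest and lowest line was 3.05-fold, 1372 had at least a 4-fold range and 267 at least a 16-fold range. The median intraclass correlation, the share of variance lying between lines, was 0.51 among these probe sets and 0.09 over all probe sets above the median level. Of 147 named probe sets, 21 passed. None of them reached the intraclass correlation of 0.8 set for the first group of named genes, so the named genes here came from the gene lists and from the other named probe sets that passed. Among these, the beta-amylase gene BMY1 differed 1.82-fold between B11 and E5 (adjusted p = 0.0212, and 0.156 with scan day in the model, the highest over the alternatives). The deoxymugineic acid synthase gene DMAS1, the glutathione transferase gene GSTZ1 and the phosphomannomutase gene PMM had ranges of 1.64-fold to 1.95-fold, and their calls were lost on leaving out any 1 of 5 arrays for each of 2 DMAS1 probe sets, of 7 for GSTZ1 and of 30 for PMM. The total was 10729 without the H8 replicate 1 array, 4717 without 4 lines whose replicate arrays disagreed (below) and 4167 without line H8.

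By gene list, 10 of 19 probe sets of the inhibitor, thionin and serpin symbols had a genotype effect, and all 10 were highest in F36, but none of them without F36 replicate 1, when 9 were highest in F87, and 5 of them without H5 replicate 1. The 10 were of ATI, THI1.1, THI1.2, CIII and Pur-A1, and no serpin probe set passed. Random lists matched on mean level held 1.41 on average (adjusted permutation p = 0.0024 over 12 lists), and with 1 probe set per gene 6 of 13 passed (adjusted permutation p = 0.0024). The random lists take members as independent, whereas these 10 rose together in the same lines. Both p are therefore too small, and the 10 do not count as separate effects. The starch and sugar symbols had 5 of 15 probe sets past the threshold, namely GBSS, both 6-FEH probe sets, BMY1 and PMM. That share did not pass against matched lists (adjusted permutation p = 0.088), although it passed by Fisher's exact test (adjusted p = 0.0136). Of the list of grain protective proteins fixed before the data were examined, 2 of 5 probe sets passed, both of Pur-A1, and 1 on leaving out any 1 of 5 arrays. The matched-list test gave an adjusted permutation p of 0.0276, but with 1 probe set per gene it was 0.514 (1 of 4). Adjusted over the list alone, 10 inhibitor, 5 starch and sugar and 2 grain protective probe sets passed.

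The remaining lists did not pass against matched lists (adjusted permutation p of 0.946 or more). The storage protein symbols had 1 of 17 probe sets with a genotype effect, avnla, and 3 when adjusted over the list alone. That count rested on single arrays: it was 11 of 17 without F36 replicate 2, 3 without replicate 1 of H5, H8, F82 or C10, and 2 without F82 replicate 2. The next member by F, ALP, had an adjusted p of 0.079 (1.54e-06 to 0.169 with each array left out in turn). The lowest of these was without F36 replicate 2, and values were also below 0.05 without replicate 1 of H5, H8, F82 or C10. The photosynthesis symbols held 36 probe sets of 6 genes, most of them of 1 gene, rbcl, and 11 had a mean level above the median. With 1 probe set per gene, 0 of 6 had a genotype effect. The stress and defence symbols had 1 of 19, hsp16.9A, and the photosynthesis symbols 1 of 36, which reached the median level in no line. Without H8 replicate 1 these counts were 5 and 8. The stress and defence count was also 3 without G30 replicate 1 and 2 without G30 or DH91 replicate 2, and the photosynthesis count was 0 on leaving out any 1 of 23 arrays and 2 on leaving out any 1 of 7. The rbcl probe set Ta.3807.1.A1_at, for the large subunit of Rubisco, had an adjusted p of 0.0523, and passed when any 1 of 13 arrays was left out. No probe set passed among 10 of dehydrin and LEA symbols, 18 of histone symbols, 6 of tapetum and pollen symbols, 9 of translation symbols and 10 of tubulin symbols, or among 9 of the histones list fixed beforehand. The dehydrin and LEA count was 1 without F36 replicate 2. The closest of these by their largest F were an alpha-tubulin gene, TUBA (adjusted p = 0.0634, passing without any 1 of 11 arrays), and the translation list's CL9 (0.0911, without any 1 of 5), while the Em gene of the LEA class had 0.611 and wcH2B-8, a histone gene, 0.377. Among lists fixed beforehand with fewer than 3 probe sets, starch synthesis and heat shock and chaperones each had 1 probe set with a genotype effect, GBSS and hsp16.9A, and pathogenesis-related, pollen and anther, and dehydrins and LEA proteins had 0 (1 for the last without F36 replicate 2).

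A transcript controlled by 1 locus could divide a population of fixed lines into a low and a high class, and the next comparison counted such probe sets. Of the 4088, 15 had lines in 2 classes separated by a gap of at least 0.5 log2 units and at least 2 residual SDs, but only in 4 of the 15 did every array lie on its line's side. Their gaps ran from 0.53 to 2.91 log2 units with a median of 1.01, and a median of 19 lines lay above the gap. None of the 15 has an annotated gene, so the probe sets given here were chosen after their values were seen. Ta.9188.2.S1_at had 7 lines up to 4.59 and 32 lines from 7.50 upward. TaAffx.58902.1.S1_x_at had 19 lines above and 20 below a gap of 1.66, and ran from 4.14 ± 0.04 in F44 to 10.28 ± 0.10 in F29, a 70.5-fold range. Its arrays lay on opposite sides in H9 (4.33 and 9.72, whose mean of 7.03 is the lower edge of the gap) and in C58 (4.42 and 8.04). The low classes of both lay at least partly below 5.07, so these differences too hold for intensities only. Ta.6215.1.A1_at had 20 lines above and 19 below a gap of 1.83. Ta.12020.1.A1_at had 26 above and 13 below a gap of 1.59. By an exact binomial test, 4 of the 15 departed from equal classes after adjustment, with 6, 7 or 32 lines above, and 9 had 15 to 24 lines above. The count was 125 without the 4 lines whose replicate arrays disagreed, where removing 4 other lines at random gave a median of 18 and at most 35 in 99 draws, and 27 without H8. Single arrays also moved it: 32 without either H9 array, 25 without B33 replicate 2 or H8 replicate 2, 24 without H8 replicate 1 and 23 without F82 replicate 1.

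Probe sets under 1 locus would also divide the lines alike. Among the 105 pairs of these probe sets, 3 divided the 39 lines identically, and the highest number in 1000 random draws was 0 (permutation p = 0.001, the smallest possible). The draws took the splits as independent, so a single identical pair would have given the same p. It cannot separate a shared locus from several probe sets of 1 transcript. In 2 of the 3 pairs both probe sets belonged to the same UniGene cluster, Ta.12020 or Ta.9188. The third pair was Ta.28446.1.S1_at with Ta.30774.1.S1_at, each with 19 lines above and A35 highest, at 8.48 ± 0.06 and 7.57 ± 0.05. Without the 4 lines whose arrays disagreed there were 77 such pairs among 7750, or 0.994% against 2.86% of the 105.

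Each line was then compared with the mean of the other lines, to see which stood apart. Line H8 differed at 19313 probe sets, 10462 higher and 8851 lower. In H8 the alpha-gliadin gene gli-2 had 6.16 ± 0.82 against 4.76 in the others (2.64-fold, adjusted p = 0.00688), the gibberellin oxidase gene GA20ox1d was higher by 0.99 log2 units (0.00105) and the ubiquitin-conjugating enzyme gene UBC1 by 1.11 (0.00325). Lower in H8 were the zinc finger gene WZF1 (−2.49, adjusted p = 0.0137), TUBA (−1.49, 0.00195) and the fructan exohydrolase gene 1-FEH (−1.22, 0.00299). WZF1, at 5.25 and 4.20 against 7.22 in the others, and gli-2, at 5.58 and 6.75 against 4.76, lay on the same side on both H8 arrays. So did TUBA, at 6.39 and 8.22 against 8.79, with replicate 1 the farther array. GA20ox1d (6.11 and 7.99 against 6.06) and 1-FEH (others at 8.53) did so too, but their replicate 1 lay close to the others. Only UBC1 had arrays on both sides of the others' mean, 5.56. The others' mean of gli-2 and the H8 mean of WZF1 (4.73) were below 5.07, so their differences hold for intensities only. The arrays lay farther apart for UBC1, with 5.32 in replicate 1 and 8.02 in replicate 2, and 1-FEH, with 8.50 and 6.12. Without H8 replicate 2 the count was 58, and 5 of these 6 genes lost their call, with differences of −0.25 for UBC1, which turned, 0.04 for GA20ox1d, −0.03 for 1-FEH, 0.82 for gli-2 and −1.97 for WZF1. TUBA kept its call there and lost it without H8 replicate 1 (−0.58). With array weights the count was 0. An H8 array had the lowest weight, 0.179, but with 2 arrays per line the weights cannot tell which of them departs. Other values pointed to replicate 2. It had the highest median of all arrays, 36.4 intensity units, against 32.8 for H8 replicate 1. On the first principal component of probe sets above the median level it lay at −84.5, the lowest of all arrays, and replicate 1 at −28.2. The H8 count thus rested mainly on 1 array that stood apart.

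Line A35 followed with 1307 probe sets, 1029 higher and 278 lower. Its 3 named genes were all lower: LTP3, a lipid transfer protein gene, had 13.06 ± 0.11 against 13.76 in the others (1.62-fold, adjusted p = 0.0367). Prx1 differed by −0.55 (0.0389; 4.57 in A35, below 5.07, so for intensities only) and cys1 by −0.50 (0.0296). Each lay below the others' mean on both A35 arrays, and each lost its call without either array and with scan day in the model. The A35 count was 109 without its replicate 1, 305 without its replicate 2 and 65 with scan day as a fixed term. F36 had 558, A81 413, B33 386 (its arrays agreed at 60.3% of splits) and DH91 303, the median line had 73, and F38a with 1 and F82 with 8 had the fewest. The median was 350 without the 4 lines whose arrays disagreed, and leaving out a single array of G30 or H9 gave 117 to 121.

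**Figure D2:**
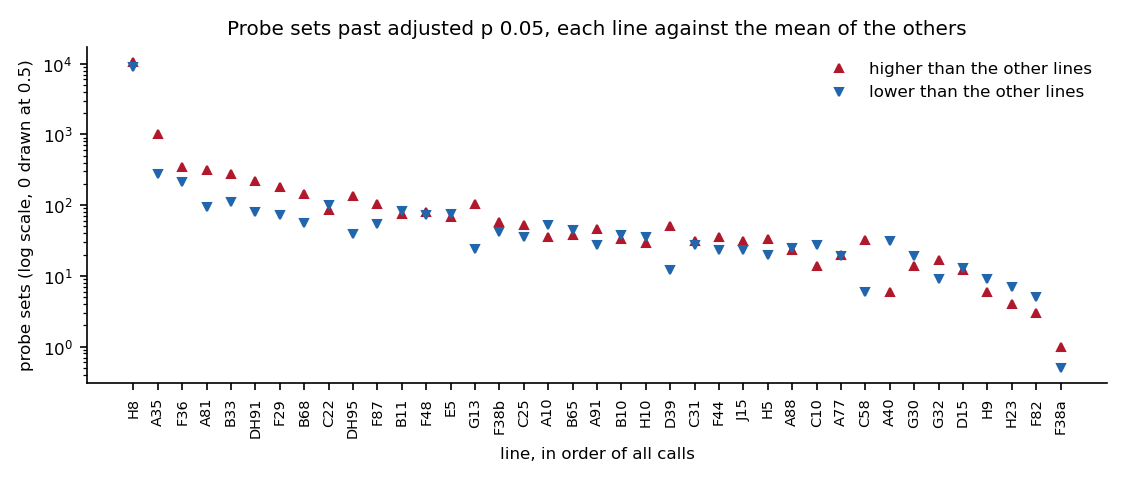
Number of probe sets past an adjusted p of 0.05 in each of the 39 lines against the mean of the others, on a log axis, with higher (red) and lower (blue) probe sets apart and lines ordered by their total. H8 reached 10462 higher and 8851 lower, and F38a had 1.

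The labels give F38a and F38b the same stem without saying how these lines are related. F38a had higher levels of 3 probe sets, none with an annotated gene, which were chosen for the text because they were all that passed. TaAffx.58902.1.S1_x_at had 8.69 ± 0.62 in F38a and 4.25 ± 0.17 in F38b (21.7-fold in intensity, with F38b below 5.07; adjusted p = 0.0268). Ta.22975.1.S1_at had 12.00 ± 0.72 and 9.33 ± 0.32 (6.38-fold, 0.000737), and Ta.10426.1.A1_at had 7.36 ± 0.11 and 6.03 ± 0.16 (2.51-fold, 0.0412). None of 147 named probe sets passed. Of 61115 probe sets, 1626 had an unadjusted p below 0.05 in limma, a smaller share than the 0.05 that would arise with no difference. This pair ranked 4 from the fewest calls among all pairs of lines, and the median pair gave 181. The pairs with 0 calls, C22 with H9 and G13 with G30, hold arrays whose labels are doubted below. The correlation of the F38a and F38b line means was 0.52, against a median of −0.03 over all pairs. Each of the 3 probe sets lost its call on leaving out any 1 of at least 2 of the 4 F38 arrays, although the differences stayed between 4.00 and 4.88, 2.17 and 3.18, and 1.22 and 1.44 log2 units in the order given. The count was 17 without F38a replicate 1, 6 without F38b replicate 1, 0 without F38b replicate 2, and 5 without any 1 array of H9, D39 or C58. It was 12 without the 4 lines whose arrays disagreed.

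The replicate numbers were compared with lines as blocks. The instrument files place all 39 replicate 2 arrays in an earlier hybridization campaign and all 39 replicate 1 arrays in a later one, so replicate number and campaign cannot be told apart. FKBP70, an immunophilin gene, was higher in replicate 2, 11.21 ± 0.26 against 10.75 ± 0.30 (SD, n = 39; higher in 34 of 39 lines, limma adjusted p = 5.89e-07). The calcium channel gene TaTPC1 was higher by 0.51 log2 units (32 of 39 lines, 1.38e-05), an rbcl probe set by 0.42 (32 lines; 4.02 against 3.60, both below 5.07 and not shown to exceed background), the histone gene H2A-3 by 0.33 (31 lines) and AGA.1 by 0.25 (28 lines). The cap-binding protein gene NCBP was lower in replicate 2, 10.19 ± 0.26 against 10.52 ± 0.24 (34 of 39 lines, adjusted p = 1.35e-05). Also lower were the histone gene H2A-2 (−0.48, 29 lines), the fructose bisphosphatase gene FBP (−0.35, 32 lines), the phytochelatin synthase gene PCS1 (−0.32, 27 lines) and a 6-FEH probe set (−0.29, 25 lines). Of 147 named probe sets 44 differed, 12 higher and 32 lower in replicate 2.

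Over all probe sets 17527 differed between the replicate numbers, 9454 higher and 8073 lower in replicate 2. The differences were small, with a median size of 0.19 log2 units, and 34 reached 2-fold. The 3′ minus 5′ difference of the wheat control genes, a measure of RNA integrity, averaged 2.16 ± 0.41 log2 units in replicate 1 and 2.40 ± 0.44 in replicate 2 (n = 39, higher in 26 lines, permutation p = 0.00524). With it as a covariate the count was 11095. With scan day in the fit it was 7 and none of the 10 named genes passed, but replicate and scan day then part only on 1 day with 6 replicate 1 arrays and 1 replicate 2 array, and the standard error was 7.41 times as large. With the 3′ minus 5′ covariate, FBP (−0.23) and 6-FEH (−0.11) lost their calls (limma adjusted p = 0.0635 and 0.22). Apart from that covariate and scan day, the settings gave them limma adjusted p of 0.00016 to 0.0302.

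Mean levels of lists were compared next, over members above the median level only. For example, this left 4 of 17 storage protein, 3 of 6 tapetum and pollen, 11 of 36 photosynthesis and 11 of 19 inhibitor probe sets. The inhibitor, thionin and serpin mean was highest in F36, 2.60 ± 1.46 log2 units above the mean of all arrays, and lowest in DH91, at −0.93 ± 0.04 (11.6-fold, permutation p = 0.00061, adjusted 0.00275 over 9 lists). Without F36 replicate 1 this range was 7.68-fold with F87 highest, and without F36 replicate 2 it was 23.7-fold. The starch and sugar mean ran from 0.33 ± 0.003 in A40 to −0.40 ± 0.05 in A35 (1.66-fold, permutation p = 0.00031, adjusted 0.00275). The storage protein mean was also highest in F36, 1.57 ± 1.72 (in F44, 0.43, without F36 replicate 1), and the tubulin mean was highest in B68, 0.21 ± 0.11, but neither passed (adjusted permutation p = 0.116 for both). The storage protein mean passed without F36 replicate 2 (0.006, against 0.006 to 0.334 over all arrays left out in turn), and the tubulin mean without H23 replicate 2 (0.0315, against 0.0315 to 0.253). The starch and sugar call was lost with the median over members (0.163, against 0.0009 to 0.163 over the settings). The tapetum and pollen, translation, stress and defence, histone and photosynthesis means gave adjusted permutation p of 0.384, 0.444, 0.621, 0.689 and 0.772. These tests took no account of the replicate number. With it as a replicate block the tapetum and pollen mean passed (adjusted permutation p = 0.0069, against 0.0069 to 0.793 over the settings), as did the tubulin mean (0.0495, against 0.0394 to 0.457). Both also passed with values centred within scan day (0.0157 and 0.0394), and the tapetum and pollen mean with all members (0.0465). In replicate 2 the tapetum and pollen mean was lower by −0.11 (lower in all but 6 of 39 lines), the stress and defence mean by −0.14, the photosynthesis mean by −0.11 and the starch and sugar mean by −0.09, while the tubulin mean was higher by 0.06 in 25 lines. In a permutation of signs the adjusted p of these 5 ran from 9e-05 to 0.0268, and the histone, inhibitor, storage and translation means did not pass.

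Correlations between list means were taken over the 39 line means for 36 pairs of lists, and 4 pairs passed by Pearson's r. Inhibitor and storage protein means were positively correlated, with r = 0.68 (permutation p = 1e-05, the smallest possible, adjusted 0.00036) and Spearman rho = 0.55 (permutation p = 0.00032, adjusted 0.00576). Without the 2 farthest lines r was 0.57, within replicate 1 it was 0.74 and within replicate 2 0.70. When the inhibitor mean of 1 replicate was set against the storage mean of the other, r was 0.23. The photosynthesis mean was correlated with the stress and defence mean (r = 0.60, rho = 0.57), the starch and sugar mean (r = 0.53, rho = 0.41) and the tapetum and pollen mean (r = 0.51, rho = 0.52). Their permutation p were 6e-05, 0.0005 and 0.00108 for r, or 0.00108, 0.006 and 0.00972 adjusted, and 0.00015, 0.00999 and 0.00061 for rho, or 0.0054, 0.0514 and 0.00732 adjusted. Without the 2 farthest lines r was 0.46, 0.36 and 0.46, within replicate 1 it was 0.43, 0.37 and 0.44, and within replicate 2 it was 0.69, 0.57 and 0.51. Across replicates these r were 0.14, 0.22 and 0.15, and with all members of each list, dim ones included, they were 0.08, 0.15 and 0.15. The photosynthesis and the starch and sugar lists share 2 probe sets, both of FBP, and without these their r was 0.41. For photosynthesis with stress and defence, starch and sugar, and tapetum and pollen, differences between replicates were also correlated (r = 0.52, 0.42 and 0.44). Their adjusted permutation p were 0.00882, 0.0357 and 0.0306 for r, and 0.0401, 0.105 and 0.105 for rho. Over lines, the photosynthesis means of the 2 replicates had r = 0.06. These lists thus varied together between arrays of a line, so their correlations were not shown to lie between genotypes. The storage protein mean had r = 0.26 with starch and sugar (permutation p = 0.12, adjusted 0.271; rho = 0.47, adjusted 0.0264) and r = 0.23 with photosynthesis (permutation p = 0.145, adjusted 0.274; rho = 0.43, adjusted 0.0407). Inhibitor with photosynthesis also passed by rho alone (r = 0.36, permutation p = 0.0242, adjusted 0.129; rho = 0.45, adjusted 0.0291). Relations with cell division and with nucellus and pericarp breakdown could not be computed, since those lists had no members in the annotation.

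**Figure D3:**
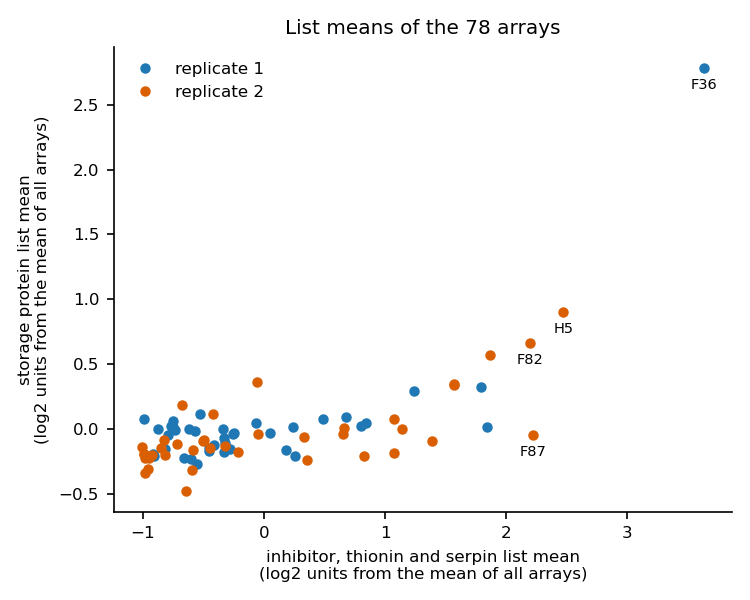
Mean of the inhibitor, thionin and serpin list (horizontal) and of the storage protein list (vertical) on each of the 78 arrays, in log2 units from the mean of all arrays, replicate 1 in blue and replicate 2 in orange. The F36 replicate 1 array lies at 3.63 and 2.78, and the 4 arrays with the highest inhibitor means carry their line's name.

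Agreement between replicate arrays was examined last. Over probe sets above the median level, 23 of 78 arrays had the other array of their line as their nearest (1.01 by chance), and 48 were nearest to an array of the same replicate number. With values centred within each replicate number, 39 were nearest to their own line. A panel of 145 probe sets that divide the 78 arrays into 2 clusters was then chosen without using the line labels, and reduced to 73 distinct splits. On it 65 arrays were nearest to their own line, and 19 lines had replicate arrays agreeing at 95% or more of the splits. Arrays of different lines agreed at a median of 52.1%, with a central 95% from 38.4% to 67.1%. The replicate arrays of H9 (38.4%), G30 (41.1%), G13 (42.5%) and B33 (60.3%) agreed no better than that, and the next lines were H23 (69.9%) and H8 (71.2%). The array labelled G30 replicate 1 matched that labelled G13 replicate 2 at 98.6%, and G30 replicate 2 matched G13 replicate 1 at 100%. The array labelled H9 replicate 1 matched the C22 arrays at 97.3% and 98.6%, while H9 replicate 2 matched them at 41.1% and 39.7%. The panel's settings and the limit were chosen after the data were seen, and the labels were kept as deposited in all counts unless stated otherwise.

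**Figure D4:**
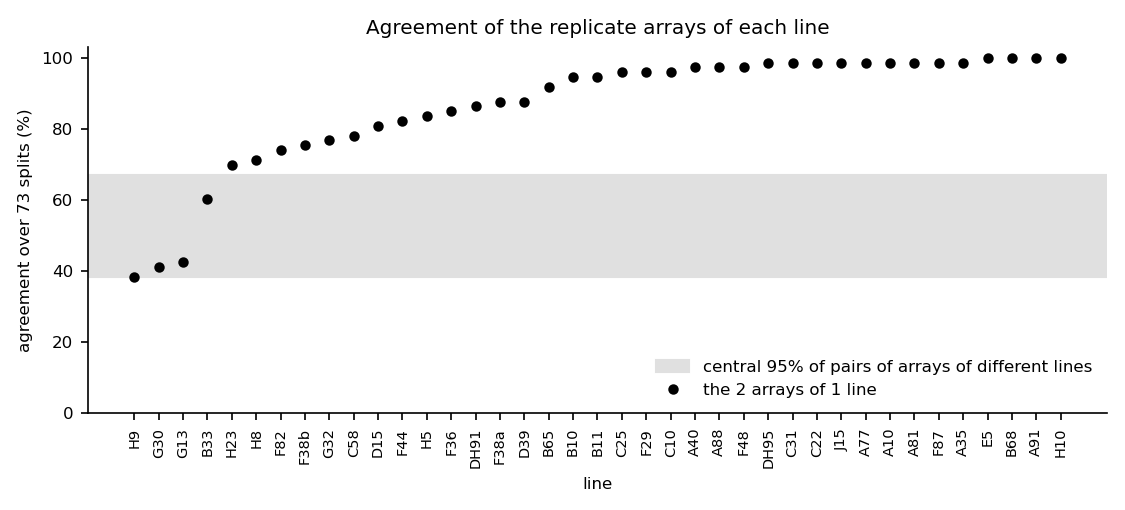
Share of 73 splits at which the replicate arrays of each line fell on the same side (points), lines ordered by that share, with the central 95% of pairs of arrays from different lines (grey band, 38.4% to 67.1%). H9, G30, G13 and B33 lie inside the band.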

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

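All tests of the 4 lines whose arrays disagree, the random splits behind the genotype effect and the replicate comparison, the test of the campaign, the comparison of controls between replicates and the limit for the spike-in controls were chosen only after the results were seen.

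The poly(A) spike-in control probe sets, which lie outside the wheat transcripts, stood 4.16 log2 units (17.9-fold) above their median on the array labelled F29 replicate 2, averaged over 36 probe sets. All 36 were highest on that array and 21 were at least 4 log2 units above their median there, and the next array, C22 replicate 2, stood 2.29 above it (4.89-fold).

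The replicate arrays of H9, G30, G13 and B33 agreed at 38.4%, 41.1%, 42.5% and 60.3% of 73 label-free splits, no better than arrays of different lines. Degraded RNA is argued against as the shared cause, since 1 of the 8 arrays lay outside the central 95% (1.55 to 3.05 log2 units) of the 3′ minus 5′ differences of the others. That array, G30 replicate 2, had the highest value of all arrays, 3.22. Whether an array failed was not tested, since this difference follows RNA integrity only. A candidate explanation for G30 and G13 is that their labels were exchanged in 1 replicate, since both crossed pairs agreed at 98.6% or more. For H9, seed of line C22 may be on the array labelled replicate 1, which matched the C22 arrays at 97.3% and 98.6%. For B33 an exchange with H8 in 1 replicate stays open: the crossed pairs agreed at 83.6% and 69.9%, as high as the replicate arrays of some other lines (from 69.9%) but below the 95% set for an exchange, and the data do not tell which of the paired labels is right.

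The second pattern is the difference between replicate 2 and replicate 1 at 17527 probe sets. Chance can be excluded, since only 1 of 100 splits, the real one, gave as many calls, and the highest of the others gave 1791. Lower RNA integrity in replicate 2 stays open: with the 3′ minus 5′ difference as a covariate 53.8% of the calls were kept, which lies between what was set beforehand for and against it. Array processing campaign and replicate number cannot be told apart, because 0 replicate numbers occurred in both campaigns, and controls differed with it: 18S rRNA was higher by 1.00 log2 units in replicate 2 (30 of 39 lines) and the spike-in controls by 0.62 (28 lines), with replicate 2 giving the 18 arrays of highest spike-in signal. A difference between field replications, days or seed stages was not tested apart from these and stays open.

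The third pattern is the genotype effect and the 15 probe sets that divide the lines into 2 classes. Chance can be excluded for the genotype effect, since only 1 of 100 splits, the real one, gave as many calls and the other pairings of arrays at most 107, while their highest 2-class count of 0 (again 1 of 100 as large) adds no separate evidence, since 2 classes were sought among those few calls. Base differences under the probes may give 2 classes where transcript levels are alike; the median correlation with other probe sets of the same cluster was 0.79, but only 1 cluster had such partners, so this stays open. Cross-hybridization with close copies also stays open, with an odds ratio of 0.87 for the suffixes that mark shared probes (4 of 15 against 1202 of 4073, 95% limits 0.201 to 2.94, Fisher's exact p = 1). A locus segregating between the parents, the biological explanation that the cross gives, was not tested, since no genotypes of the lines were analysed here.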

How the results depend on the processing

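The alternatives that leave out lines or the 3 arrays with a differing wash record, exchange labels, use the 3′ minus 5′ covariate or label-free splits, or add scan day to the replicate comparison were chosen after the data were seen. Of 72 values of the main counts under alternatives, 42 stayed within 1.5 times and 30 did not. In the order genotype effect, 2-class probe sets, median calls per line, and F38a against F38b, the counts as reported were 4088, 15, 73 and 3. A further quantile normalization gave 6 for F38. Scan day as a fixed term gave 29 per line and 6 for F38, and as a random block 6341, 111 per line and 5 for F38. Array weights gave 195 per line and 1 for F38. Without the 3 arrays with a differing wash record there were 10139 and 25 2-class probe sets. Without the 4 lines whose arrays disagree there were 125 2-class probe sets, 350 per line, 12 for F38 and 77 identical splits in place of 3 (0.994% of pairs in place of 2.86%), and a replicate block on top gave 6313, 132, 416 and 12. Removing 4 other lines at random gave at most 4272 and 35 in 99 draws, so fewer lines alone did not give the rise. Without H8 there were 27 2-class probe sets, and with G30 and G13 exchanged 38 and 217 per line. An adjusted p below 0.01 left 2503. A gap of 1 log2 unit left 8 2-class probe sets, every array on its line's side 4, and 1 probe set per cluster 1 identical split. For stricter thresholds and removed probe sets the construction gives the fall. A rise on removing disagreeing or pairing matching arrays follows from their choice. The rise without the 3 arrays cannot be ascribed to the wash, since they include H8 replicate 1, which gave a like rise when it alone was left out. Both removals left H8 with its replicate 2 array alone, and leaving out the whole line gave no such rise in the genotype effect. For the others the cause was not tested.

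Replicate 2 against 1 fell from 17527 to 11095 with the 3′ minus 5′ covariate. Campaign equals replicate number and could not be added. Scan day left 7, with the effect resting on 1 day (1 replicate 2 array, 6 replicate 1 arrays) and a standard error 7.41 times as large; none of the 10 named genes passed and 7 changed sign (TaTPC1 −0.48, FKBP70 −0.12, rbcl −1.36, H2A-3 −0.49, AGA.1 −0.34, FBP 0.63, 6-FEH 0.82). Nearest arrays of the same line went from 23 to 1 without the called probe sets, to 39 with a replicate block and to 65 on label-free splits. The replicate block alone moved no other main count by over 1.5 times (5622 for the genotype effect, 17, 97 and 3), but it gave the tapetum and tubulin list means a call (0.0069 and 0.0495).

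Leaving out each array in turn gave 3601 to 10729 for the genotype effect (10729 without H8 replicate 1), 13 to 32 2-class probe sets (32 without either H9 array, 25 without B33 or H8 replicate 2, 24 without H8 and 23 without F82 replicate 1), 60 to 121 per line (117 to 121 without an array of G30 or H9) and 0 to 17 for F38 (0 without F38b replicate 2, 6 without its replicate 1, 17 without F38a replicate 1, 5 without any array of H9, D39 or C58). UBC1 in H8 ran from −0.25 without replicate 2, the only reversal on leaving out an array, to 2.46 without replicate 1.

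Of 460 adjusted p of named genes for the genotype effect 14 lost and 25 gained a call, of 154 contrasts 19 lost one and 7 more reversed, of 81 list means 1 lost and 5 gained one, of 24 tests against matched lists 2 lost and 1 gained one, and of 221 list member counts 41 and of 216 list correlations 7 moved. The share with a genotype effect was 10.9% above and 2.51% below the median level; signal over background was not tested as the cause.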

Other observations

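The correlations of replicate differences, the comparison of 18S rRNA and of spike-in controls between replicates, and the label-free splits were chosen only after the results were seen.

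The inhibitor and storage protein means differed between the replicate arrays of some lines. On the F36 arrays the inhibitor, thionin and serpin mean was 3.63 in replicate 1 and 1.57 in replicate 2, and the storage protein mean 2.78 and 0.35. The H5, F82 and F44 replicate 2 arrays had inhibitor means of 2.47, 2.20 and 1.87 and storage means of 0.90, 0.66 and 0.57. Over the 39 lines the differences between replicates of these lists were correlated (r = 0.73, permutation p = 1e-05, the smallest possible, adjusted 0.00036 over 36 pairs; rho = 0.56, permutation p = 0.00033, adjusted 0.0119). Without the 2 farthest lines r was 0.65. The differences of 8 of 36 pairs of lists passed. The labels give no stage for the seed of each array beyond the day, so stage could not be examined.

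The 18S rRNA control probe set, a target that poly(A) purification should deplete, ran from 8.15 log2 units on F38b replicate 1 to 12.58 on DH95 replicate 2, a 21.6-fold range. It averaged 10.22 ± 1.06 in replicate 1 and 11.22 ± 0.90 in replicate 2 (n = 39), higher in replicate 2 in 30 of 39 lines by 1.00 log2 units on average (permutation p = 0.00012). The spike-in controls stood on average −0.18 ± 0.37 log2 units from their median in replicate 1 and 0.44 ± 1.06 in replicate 2, higher in replicate 2 in 28 of 39 lines (permutation p = 0.00087), and the 18 arrays with the highest mean were all of replicate 2.

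On the label-free splits B33 and H8 stood near each other: B33 replicate 2 matched H8 replicate 1 at 83.6% and B33 replicate 1 matched H8 replicate 2 at 69.9%, where the H8 arrays matched each other at 71.2%. F38a and F38b arrays matched at 72.6% to 76.7%, while the F38a arrays matched each other at 87.7% and the F38b arrays at 75.3%. The same 4 lines fell below the limit with panel gaps of 0.4 and 0.8, and at a gap of 1 H23 joined them. Planned tests of whether probe sets that divide the lines alike lie on 1 chromosome could not be run, as 0 of the 15 have an annotated gene, and the share of such pairs within 1 cluster, 2 of 3, lay between the bounds set beforehand.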
